A study of Mus musculus with 45 samples.

How the data were processed

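The data were expression profiles of macrophages sorted from skeletal muscle of male C57Bl6 mice that did (DTR+) or did not (DTR−) carry Foxp3.DTR, a diphtheria toxin receptor placed under the Foxp3 promoter so that the toxin (DT) removes regulatory T cells. Samples were taken at day 0, 1, 4 or 7 of a cardiotoxin injury, and RNA of 45 sorted samples was hybridized to Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, cells were Ly6g− CD11b+ F4-80+ and were split by major histocompatibility complex class II (MHCII). The gate of the 8 h day 7 set and of the day 1 and day 4 samples also left out SiglecF+ cells; the other gates list no such step. Ages were 12 weeks in the 8 h set, 10 weeks at day 0 and in the day 7 samples with no DT time in their labels, and 8 weeks elsewhere. The labels do not say what moment the 8 h and 24 h are counted from.

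Groups were taken from the sample titles. A separate marker entry of the labels reads MHCII− for all samples but the day 0 MHCII+ ones, which contradicts the titles, so the titles were checked on the arrays. H2-Ab1 lay at log2 13.67 to 14.01 in the arrays titled MHCII+ and at 7.81 to 12.45 in those titled MHCII−; 24 of 24 MHCII+ arrays lay above each of the 21 MHCII− arrays, and the same held for H2-Aa, H2-Eb1 and Cd74. The genotype could not be checked in this way: the arrays carry no probe for the human receptor of the transgene, and mouse Hbegf does not stand in for it.

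The deposited values were intensities on a linear scale, 1 per transcript cluster (probe set) and array, summarized with Affymetrix Power Tools and RMA per the labels; the versions are not given in the sources used here. They ran from 9.43 to 24649, with array medians from 174.7 to 203.7, and no 2 arrays were identical. The values were converted to log2 intensity. Of 24922 probe sets, 22824 were listed with a gene; 21425 had 1 symbol, 1399 had several and 2098 were not listed. Where a gene had more than 1 probe set, that with the highest mean was kept and 1673 were left out, which gave 19752 genes. A gene was tested when its mean in at least 1 group reached the median of all values, log2 7.57 (190 on the linear scale), which left 11074 genes. Symbols came from the probe annotation given with the series; gene coordinates and a genome build were not used here. For arrays, the number of samples per group and not a depth limits the precision.

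Differences were tested in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 45 arrays and 18 groups (27 residual degrees of freedom), an intensity trend in the moderated variance, and Benjamini-Hochberg adjustment within each comparison; an adjusted p under 0.05 passed. The spread is thus shared across sets. The residual SD was 0.20 in the 24 h day 7 set, 0.16 in the 8 h set, 0.10 at day 0 and in the day 7 samples with no DT time, and 0.11 at days 1 and 4. Comparisons were DTR+ against DTR− (7), MHCII+ against MHCII− in DTR− mice (5), days against each other in DTR− mice (5) and differences between 2 genotype effects (4). The labels do not state that samples come from separate animals, so the p-values measure the spread between samples.

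Gene lists (28 lists, 546 genes, 438 of them above the filter) were written before the data were examined, as were the comparisons, the filter, the threshold, the rule for named genes and the alternatives, except where a choice is said to be later. Lists were tested with camera (correlation between genes set to 0.01, adjusted over the lists of a comparison), which asks whether a list ranks above or below the other genes. Camera with a correlation estimated from the residuals is given beside it, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, was run too. "Adjusted over the list alone" means Benjamini-Hochberg adjustment among the members only. Overlaps of gene counts are given with the number that independent draws from the tested genes would give. Figures were drawn with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

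Genes named for a comparison were up to 10 in each direction with the largest log2 change among those that passed and whose values did not overlap between the groups (up to 5, past the threshold, for differences of effects); up to 4 members with the smallest p of each list described; and a fixed set of class II, interferon and activation genes. Predicted genes, small RNA genes and receptor segments were counted but not named under the first part.

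Same-numbered samples might come from 1 animal, which the labels do not state. For MHCII+ and MHCII− samples of DTR− mice in the 8 h set, the 3 same-numbered pairs deviated together from their group means (correlations across genes 0.480, 0.527 and 0.583), so this comparison is also given with a replicate block. The difference of effects between the subsets at 8 h holds these pairs too, and its main results come from the fit without a block. In the other comparisons the numbers did not pair the samples by this check, or fewer than 3 numbers were shared.

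The model was tested on simulated data with 200 changed genes among 11074 and the same groups. At a true log2 change of 1, the share recovered was 94.0% for 24 h MHCII+, 97.0% for 24 h MHCII−, 94.5% for 8 h MHCII+, 95.0% for 8 h MHCII− and 90.5% for the day 7 samples with no DT time. At 0.5 it was 49.5%, 50.0%, 49.5%, 55.5% and 19.5%, and none was called in the wrong direction. The simulated noise was normal and independent, with 1 SD per gene for all arrays. In the data the residual SD differed between sets, 0.20 in the 24 h set and 0.10 at day 0 and in the day 7 samples with no DT time. These shares are therefore not the recovery to be had within a given set.

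Alternatives tried were another filter at a linear 120 and no filter, quantile normalization applied again, array quality weights, a fit on the compared arrays only, a replicate block, and leaving out each array in turn. The filter at 120 was planned as the stricter 1 but let through 13804 genes and was in fact looser. Leaving out 2 arrays that stand apart, a term for the range of replicate numbers, and the score of 8 h MHCII− arrays from genes chosen without the same-numbered MHCII+ array, were added after the data were seen. Probe sets that name no single gene were tested apart and are given only as counts.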

Results

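The 45 arrays fell into 18 groups of muscle macrophages. In the 24 h day 7 set there were 2 DTR+ and 4 DTR− MHCII+ arrays and 3 and 3 MHCII− arrays; in the 8 h day 7 set 3 and 3 MHCII+ arrays and 3 and 4 MHCII− arrays. Day 1 held 2 arrays of each genotype and subset, days 0 and 4 held 2 DTR− arrays per subset, and a day 7 set with no DT time in its labels held 2 DTR+ and 2 DTR− MHCII+ arrays. Array medians ran from 174.7 to 203.7 intensity units, and the number of arrays limits the precision. Arrays of the same group correlated at 0.933 to 0.997 (median 0.982), and the first 3 principal components held 37.0%, 13.6% and 9.07% of the variance. The macrophage genes Adgre1 (F4/80), Csf1r and Cd68 were high in both subsets, with Adgre1 at log2 12.40 to 13.24 in MHCII+ and 12.56 to 13.13 in MHCII− arrays. Foxp3 and Ifng lay below the intensity filter in all groups and were not tested, and the genotype labels cannot be checked from these arrays. Changes are log2 differences ± SE.

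The first comparison asked what differed between DTR+ and DTR− mice at day 7 in the 24 h set. The residual SD of this set (0.20) was wider than that over all arrays (0.16). The shared spread thus tends to make p-values within this set too small. For both subsets and their difference, 554 is then too low a chance figure, and a count above it is not taken as an excess. In MHCII+ macrophages 6 genes rose and 0 fell (2 against 4 arrays; limma, 716 genes with an unadjusted p under 0.05, 554 by chance). Ccl17, which encodes a ligand of CCR4, rose by 1.49 ± 0.26 (adjusted p = 0.0097), from a mean of 9.44 to 10.93. The interferon-inducible GTPase genes Iigp1 and Gbp2b rose by 1.47 ± 0.30 and 1.16 ± 0.22 (adjusted p = 0.045 and 0.023). Batf2, a transcription factor gene of the interferon response, rose by 0.79 ± 0.11 (5.2e-04), Socs1, a feedback inhibitor of cytokine signalling, by 0.55 ± 0.11 (0.045), and the phosphatase gene Dusp10 by 0.60 ± 0.12 (0.045). The T cell attractant genes Cxcl9 (0.90 ± 0.37, adjusted p = 0.76) and Cxcl10 (0.65 ± 0.32, 0.77) did not pass, nor did Stat2 (0.73 ± 0.17, 0.14) or Gbp7 (0.92, 0.14). H2-Ab1 (0.03) and Mrc1 (0.15) did not pass either. The cells were sorted on MHCII, so the flat value of H2-Ab1 says little on class II.

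As a group, the IFN-γ-induced genes ranked above the other genes in 24 h MHCII+ macrophages. The median over 34 members was 0.51, with 34 of 34 above 0 (camera adjusted p = 4.9e-23; 0.0073 with an estimated correlation). Of these, 3 rose (Batf2, Iigp1 and Socs1), 0 fell and 31 did not pass; 20 passed when adjusted over the list alone, each of them higher. The median of type I interferon-stimulated genes was 0.36 (1.9e-09; adjusted p = 0.45 with an estimated correlation), with 0 of 26 passed and 1 when adjusted over the list alone. For MHC class I presentation it was 0.26 (3.7e-04; 0.22 with an estimated correlation), with 0 of 15 passed, and 0 over the list alone. Oxidative phosphorylation genes ranked lower (median −0.14, 0 of 27 passed; 1.9e-06, and 0.45 with an estimated correlation), a call that ended without DTR+ replicate 5 (median 0.00, 0.36); the median was −0.36 without DTR+ replicate 1 and −0.09 without DTR− replicate 1. The MHC class I median was 0.12 without DTR+ replicate 1. Among lists of other cells, fibroblast genes ranked lower (median −0.18, 0 of 12 passed, 0 over the list alone; 1.2e-04, and 0.45 with an estimated correlation), with medians of −0.38 without DTR+ replicate 1, −0.09 and −0.31 without DTR− replicates 1 and 4, and no call without DTR+ replicate 5 (0.05, 0.70). Endothelial genes ranked higher (median 0.11, 0 of 7 passed, 2 over the list alone, both higher; 0.015, and 0.14 with an estimated correlation), a call that ended without DTR+ replicate 1 (0.13, 0.19) or DTR− replicates 2 (0.09, 0.13) and 4 (0.20, 0.071). The neutrophil list lay at 7.79 in DTR− replicate 3, against 6.88 to 7.00 in the other 3 DTR− arrays. The count of 6 became 0 without DTR+ replicate 1, 3 without DTR− replicate 1, 2 without DTR− replicate 3 and 10 without DTR− replicate 4. With array quality weights it was 1, and with a fit on the compared arrays only 0. Without DTR+ replicate 1, Ccl17 stood at 0.96 (adjusted p = 0.27), Gbp2b at 0.70 (0.33) and Socs1 at 0.32 (0.38), each over 1.5 times smaller, while Batf2 stood at 0.79 (0.055), Iigp1 at 1.28 (0.27) and Dusp10 at 0.66 (0.18). Calls were also lost for Gbp2b without DTR− replicate 3 (0.11), for Iigp1 without DTR+ replicate 5 (0.17) and DTR− replicates 1 (0.18) and 3 (0.22), for Dusp10 without DTR+ replicate 5 (0.76) and DTR− replicates 1 (0.24) and 3 (0.19), and for Socs1 without DTR− replicates 1 (0.18), 2 (0.059), 3 (0.11) and 4 (0.057).

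In MHCII− macrophages of the 24 h set (3 against 3 arrays), 1 gene rose and 0 fell (limma, 717 genes with an unadjusted p under 0.05, 554 by chance). The gene was BC023105, at 2.32 ± 0.40 (adjusted p = 0.020). Iigp1 (1.35 ± 0.28, 0.090), Batf2 (0.50 ± 0.11, 0.098), Gbp4 (1.46 ± 0.34, 0.22), Gbp5 (0.97 ± 0.23, 0.22) and Cxcl9 (1.44 ± 0.35, 0.29) did not pass. The IFN-γ list again ranked above the other genes, with a median of 0.31 over 34 members, 33 of them above 0 (camera adjusted p = 2.2e-25; 0.0041 with an estimated correlation); 0 members passed over all genes and 12 over the list alone, each of them higher. MHC class I presentation had a median of 0.24 (3.2e-06; 0.048 with an estimated correlation), with 0 of 15 passed and 3 over the list alone. Type I interferon-stimulated genes had a median of 0.28 (2.8e-08; adjusted p = 0.54 with an estimated correlation), and 0 of 26 passed, also over the list alone. Cell cycle genes ranked lower (median −0.31, 0 of 36 passed, 0 over the list alone; 7.6e-08, and 0.62 with an estimated correlation), among them Plk1 at −0.71 ± 0.26. Among lists of other cells, fibroblast (median 0.11; 0.018, and 0.64 with an estimated correlation) and skeletal muscle genes (0.11; 0.037, and 0.64) ranked higher, with 0 of 12 and 0 of 13 passed, also over the list alone. The fibroblast call ended without DTR+ replicates 1 (0.04, 0.096) and 3 (0.10, 0.24) or DTR− replicate 3 (0.06, 0.16), and the median was 0.17 without DTR− replicate 2. The muscle call ended without DTR+ replicates 2 (0.07, 0.10) and 3 (0.05, 0.75) or DTR− replicate 3 (0.05, 0.27), and the median was 0.17 without DTR+ replicate 1. Without DTR+ replicate 3 the IFN-γ median was 0.47, and without DTR+ replicate 1 the MHC class I median was 0.13. With array quality weights the count of 1 was 880, and with a fit on the compared arrays only it was 0. It became 0 without DTR+ replicate 2 (BC023105 at an adjusted p of 0.14) or DTR− replicate 3 (0.54), 2 without DTR+ replicate 1 and 12 without DTR+ replicate 3. Between the subsets, 0 of 11074 genes differed in the genotype effect (limma, 1012 with an unadjusted p under 0.05, 554 by chance), and the IFN-γ list did not either (median difference 0.08, adjusted p = 0.93). The count of 0 became 1 without any 1 of 4 arrays: DTR+ MHCII+ replicate 5, DTR+ MHCII− replicate 3, DTR− MHCII+ replicate 2 or DTR− MHCII− replicate 3.

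**Figure D1:**
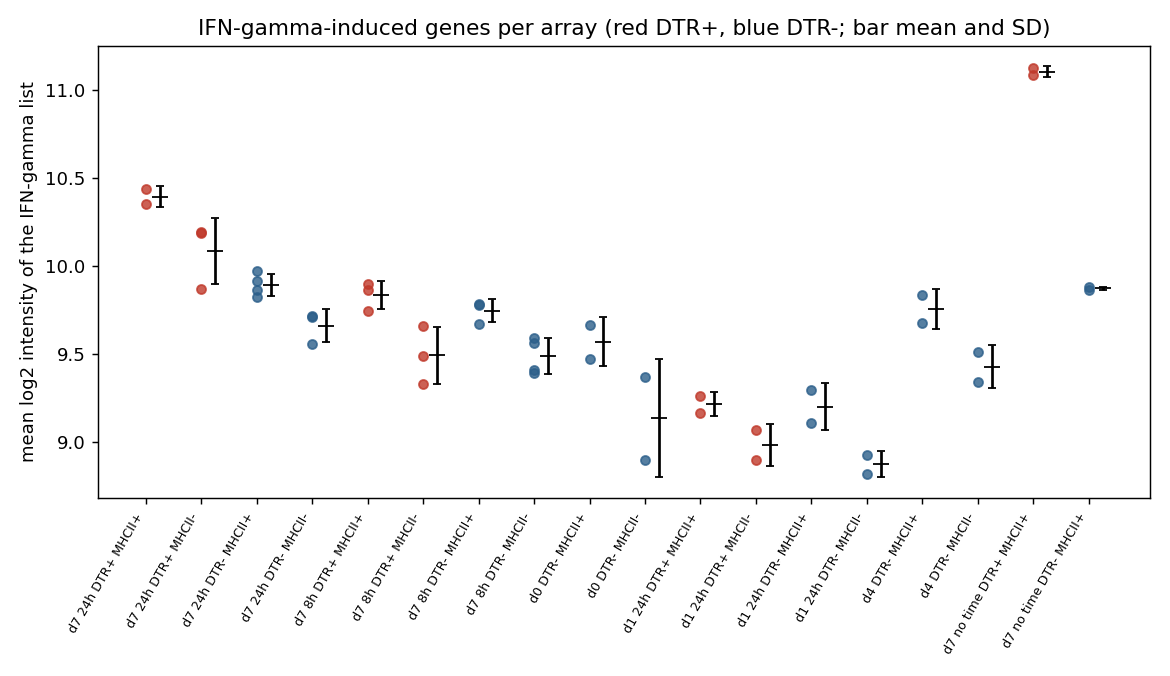
Mean log2 intensity of the IFN-γ-induced list in each array (points) by group, DTR+ in red and DTR− in blue, with bars for the group mean and SD. The median log2 difference over the list was 0.51 and 0.31 in the MHCII+ and MHCII− arrays of the 24 h set, 0.06 and 0.00 in the 8 h set, and 1.00 in the day 7 set with no DT time.

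The same question was asked of the 8 h day 7 set. In MHCII+ macrophages 43 genes rose and 11 fell (3 against 3 arrays; limma, 2044 with an unadjusted p under 0.05, 554 by chance), 8 of them at least 2-fold up. Il1a, which encodes the cytokine IL-1α, rose by 1.98 ± 0.26 (adjusted p = 8.4e-05), from 9.13 to 11.11. Il10, which encodes a cytokine that restrains macrophage activation, rose by 1.42 ± 0.23 (0.0024). The orphan nuclear receptor genes Nr4a3 and Nr4a2 rose by 1.67 ± 0.35 and 1.49 ± 0.33 (0.020 and 0.031), and the arginase gene Arg2 by 1.25 ± 0.24 (0.0099). The inflammasome sensor gene Nlrp3 rose by 1.02 ± 0.23 (0.031), the cAMP-responsive factor gene Crem by 0.96 ± 0.19 (0.015) and Il1b by 0.67 ± 0.16 (0.038). Txnip, a thioredoxin inhibitor, fell by 0.71 ± 0.15 (0.018) and the tubulin gene Tubb2a by 0.82 ± 0.19 (0.038). Cxcl9 (1.01 ± 0.35, adjusted p = 0.16) and Cxcl10 (0.91 ± 0.30, 0.15) did not pass.

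Inflammatory cytokines and NF-κB targets ranked above the other genes in 8 h MHCII+ macrophages (median 0.33, 24 of 27 above 0; camera adjusted p = 3.4e-10, and 0.29 with an estimated correlation). Of these, 3 rose (Il1a, Nlrp3 and Il1b), 0 fell and 24 did not pass; 11 passed over the list alone, each of them higher. The IFN-γ list did not pass (median 0.06, adjusted p = 0.11; 0 of 34 passed, and 0 over the list alone). Lists of other cells stood apart too: T cell genes had a median of 0.66 (0 of 8 passed, 6 over the list alone; 3.6e-05, and 0.29 with an estimated correlation), among them Cd3e at 1.09 ± 0.30, regulatory T cell genes 0.43 (0 of 4 passed, 4 over the list alone; 0.0041, and 0.29 with an estimated correlation), and cell cycle genes 0.38 (0 of 36, 0 over the list alone; 1.2e-08, and 0.72 with an estimated correlation). The median of complement and efferocytosis receptor genes was −0.28 (0 of 21 passed; 0.0099, and 0.75 with an estimated correlation). Without DTR+ replicate 1 these 4 medians were 0.07 (adjusted p = 0.25), 0.07 (0.54), 0.07 (0.20) and −0.11 (0.54), and that of NF-κB targets was 0.52. Without DTR+ replicate 3 the cell cycle median was 0.58, and without DTR− replicate 2 the complement call ended (0.066). Fibroblast (median −0.23, 0 of 12 passed, 1 lower over the list alone; 0.0068, and 0.72 with an estimated correlation) and macrophage genes (−0.14, 0 of 10, 4 lower over the list alone; 0.045, and 0.72) ranked lower. The macrophage call ended without DTR+ replicate 1 (−0.13, 0.25) or DTR− replicates 2 (−0.16, 0.066) and 3 (−0.14, 0.053).

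The count of 54 genes in 8 h MHCII+ macrophages became 9, 778 and 19 without DTR+ replicates 1, 3 and 4, and 5, 8 and 27 without DTR− replicates 1, 2 and 3. With array quality weights it was 2103, and with a fit on the compared arrays only 2. Il1a and Il10 stayed past the threshold without any 1 of the 6 arrays (1.89 to 2.08 for Il1a). The calls of Nr4a3, Nr4a2, Arg2 and Nlrp3 ended without DTR+ replicate 1, DTR+ replicate 4, DTR− replicate 1 or DTR− replicate 2, with adjusted p up to 0.18, 0.24, 0.10 and 0.28. The call of Crem ended without DTR+ replicate 1 (0.11) or DTR− replicates 1 (0.16) and 2 (0.079), that of Txnip without DTR+ replicates 1 (0.13) and 4 (0.074) or DTR− replicates 1 (0.16) and 2 (0.13). The calls of Il1b and Tubb2a ended without any of 5 arrays, DTR+ replicates 1 and 4 and DTR− replicates 1, 2 and 3 (up to 0.29 and 0.47).

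In MHCII− macrophages of the 8 h set (3 against 4 arrays), 2 genes rose and 0 fell (limma, 486 with an unadjusted p under 0.05, 554 by chance): Tnfsf18, which encodes the ligand of the co-stimulatory receptor GITR, by 1.10 ± 0.18 (adjusted p = 0.0048), and Il10 by 1.15 ± 0.21 (0.031). Il1a (1.10 ± 0.24, 0.093), Klf4 (0.59 ± 0.13, 0.093) and Tnfaip3 (0.74 ± 0.15, 0.067) did not pass. Both genes were also among the 43 that rose in MHCII+ macrophages. Independent draws would give 0.0078, but same-numbered DTR− samples of the 2 subsets deviate together, so the overlap was not tested. Immediate-early and heat-shock genes ranked above the other genes (median 0.30; camera adjusted p = 8.5e-12, and 0.22 with an estimated correlation), with 0 of 23 passed and 6 over the list alone, each of them higher. So did NF-κB targets (median 0.21; 4.2e-08, and 0.22 with an estimated correlation), with 0 of 27 passed and 9 over the list alone, while the IFN-γ list did not pass (median 0.00, 0.89; 0 of 34 members). The NF-κB median was 0.33 without DTR+ replicate 5 and 0.35 without DTR− replicate 3. Fibroblast genes ranked lower (median −0.24, 0 of 12 passed, 0 over the list alone; 9.3e-07, and 0.22 with an estimated correlation), with medians of −0.15 without DTR− replicate 2 and −0.41 without DTR− replicate 5. Oxidative phosphorylation genes ranked lower too (median −0.12, 0 of 27, 0 over the list alone; 8.5e-04, and 0.70 with an estimated correlation). Their median was −0.26 and −0.06 without DTR+ replicates 3 and 6, and the call ended without DTR+ replicate 5 (−0.02, 0.13) or DTR− replicate 3 (−0.04, 0.10). Tnfsf18 lost its call without DTR+ replicates 5 (0.087) and 6 (0.057) or DTR− replicate 3 (0.056). Il10 lost it without DTR+ replicates 3 (0.089), 5 (0.31) and 6 (0.057) or DTR− replicates 1 (0.094), 2 (0.096) and 3 (0.20). The count of 2 became 0 without DTR+ replicate 5, DTR+ replicate 6 or DTR− replicate 3, 1 without DTR− replicate 1 or 2, and 97 without DTR− replicate 5. With array quality weights it was 2492, and with a fit on the compared arrays only 0. DTR− replicate 5 stood apart from DTR− replicates 1 to 3: on the score of genes changed in the MHCII+ arrays it lay at 0.92, against 0.29, 0.23 and 0.38 in those 3 and 0.86, 1.04 and 1.00 in the DTR+ arrays. The genes of this score were chosen against DTR− MHCII+ replicates 1 to 3, and same-numbered DTR− samples of the 2 subsets deviate together, so the low values of those 3 are not independent of that choice. DTR+ replicate 3 (0.86) also shares its number with a DTR+ MHCII+ array used for the choice, so its value may not be independent either.

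**Figure D2:**
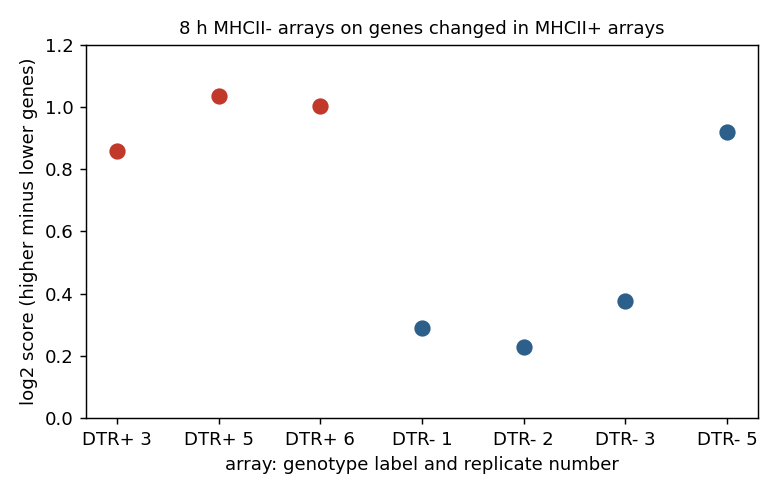
Score of each MHCII− array of the 8 h set (log2 units, from the genes that rose and fell in the MHCII+ arrays of that set) by genotype and replicate. DTR+ arrays lie at 0.86 to 1.04 and DTR− arrays at 0.23 to 0.38, except DTR− replicate 5 at 0.92. DTR− replicates 1 to 3 share their numbers with the MHCII+ arrays from which the genes were chosen, so their place is not independent of that choice. DTR+ replicate 3 also shares its number with such an array of its genotype, so its place may not be independent either.

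Differences between these genotype effects were tested directly. At 8 h, 0 of 11074 genes differed between MHCII+ and MHCII− macrophages (limma, 856 with an unadjusted p under 0.05, 554 by chance), and the IFN-γ list did not either (median difference 0.05, adjusted p = 0.14). Between the 24 h and the 8 h set, 0 genes differed in MHCII+ (1319 unadjusted) and 0 in MHCII− macrophages (538 unadjusted). The IFN-γ list differed by a median of 0.46 in MHCII+ (camera adjusted p = 8.3e-06; 0.30 with an estimated correlation) and 0.35 in MHCII− macrophages (1.8e-15; 0.052 with an estimated correlation). NF-κB targets differed the other way, by −0.29 (4.8e-08; 0.30) and −0.36 (0.0019; 0.49), the last value of each pair being that with an estimated correlation. In MHCII− macrophages the NF-κB call was lost without 24 h DTR+ replicate 1 (−0.36, 0.073), 24 h DTR− replicate 3 (−0.26, 0.13), 8 h DTR+ replicate 3 (−0.25, 0.072) or 8 h DTR− replicate 2 (−0.26, 0.074), and the IFN-γ median difference was 0.23 and 0.56 without 24 h DTR+ replicates 1 and 3. The 2 sets also differ in age and gate, so the DT time cannot be separated from these. The count in MHCII+ macrophages was 2 without 24 h DTR+ replicate 5, 55 without 8 h DTR+ replicate 3 and 2 without 8 h DTR− replicate 2; that in MHCII− macrophages was 1 without 24 h DTR+ replicate 3 and 12 without 8 h DTR− replicate 5.

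At day 1, with 24 h in the labels, 0 genes differed between DTR+ and DTR− mice in MHCII+ (2 against 2 arrays; limma, 25 with an unadjusted p under 0.05) or MHCII− macrophages (2 against 2 arrays; 154), where chance would give 554. Type I interferon-stimulated genes ranked above the other genes in MHCII+ (median 0.25, 26 of 26 above 0; camera adjusted p = 3.0e-16, and 0.47 with an estimated correlation) and MHCII− macrophages (0.31, 25 of 26; 4.1e-11, and 0.99 with an estimated correlation). In both subsets 0 of 26 members passed, also over the list alone. Without DTR+ replicate 1 the medians were 0.13 (0.23) and 0.16 (0.12), and the calls ended. The MHCII+ median was 0.38 and 0.12 without DTR− replicates 1 and 2, and the MHCII− median 0.49 without DTR+ replicate 2. Deviations of same-numbered MHCII+ and MHCII− samples at day 1 correlated at 0.29 in DTR− and 0.28 in DTR+ mice. The results of the 2 subsets may therefore not be independent, although 2 numbers are too few to tell. The NK cell and cytotoxic effector list ranked higher in MHCII+ macrophages (median 0.35, 0 of 2 passed, 0 over the list alone; 0.026, and 0.47 with an estimated correlation). Its call ended without DTR+ replicate 1 (0.28, 0.36) or DTR− replicate 2 (0.12, 0.43), and its median was 0.57 without DTR− replicate 1. The IFN-γ list did not pass (medians 0.00 and 0.12, adjusted p = 0.94 and 0.13; 0 of 34 members in both).

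By count of genes, the largest of the 7 genotype differences stood in the day 7 MHCII+ set with no DT time in its labels, where 589 genes rose and 687 fell (2 against 2 arrays; limma, 2457 with an unadjusted p under 0.05), 195 and 154 of them at least 2-fold. Chil3, which encodes the chitinase-like protein Ym1, rose by 6.74 ± 0.55 (adjusted p = 3.4e-11), from 5.44 to 12.18, and Arg1 (arginase 1) by 6.18 ± 0.61 (3.0e-09), from 6.89 to 13.07. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, rose by 5.69 ± 0.17 (9.2e-23), Gbp2b by 4.83 ± 0.25, the amino acid transporter gene Slc7a2 by 4.68 ± 0.24 and Nos2, which encodes the inducible nitric oxide synthase, by 3.08 ± 0.15 (2.1e-16). The chemokine genes Ccl17, Ccl24 and Ccl22 rose by 4.23 ± 0.30, 2.88 ± 0.29 and 2.81 ± 0.22. Hpgd, a prostaglandin-degrading enzyme, fell by 3.61 ± 0.25, Cd209f by 3.49 ± 0.52, the iron exporter gene Slc40a1 by 3.19 ± 0.45, Gas6, a bridging ligand in the uptake of dead cells, by 2.43 ± 0.23 and the scavenger receptor gene Stab1 by 1.89 ± 0.26. H2-Ab1 (0.03), Mrc1 (0.01), Il1b (0.05) and Mki67 (0.42, adjusted p = 0.54) did not pass. As these cells were sorted on MHCII, the flat value of H2-Ab1 says little.

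Glycolysis and hypoxia genes rose in this set in 23 of 23 members, also over the list alone (median 1.45; camera adjusted p = 7.3e-34, and 0.0030 with an estimated correlation), among them Pgk1 by 2.16 ± 0.23, Pfkp by 2.00 ± 0.20 and Bnip3 by 1.86 ± 0.17. Of 34 IFN-γ-induced genes 25 rose, 0 fell and 9 did not pass (27 higher over the list alone; median 1.00, 1.4e-28, and 0.0021 with an estimated correlation), with Gbp4 at 4.35 ± 0.41, Socs1 at 1.55 ± 0.13 and Cxcl9 at 2.59 ± 0.43. MHC class I presentation had 8 of 15 higher and 0 lower (10 over the list alone; median 0.57, 1.0e-06, and 0.037 with an estimated correlation). Type I interferon-stimulated genes went the other way: 0 of 26 rose and 10 fell, 13 over the list alone (median −0.66, 6.6e-07; adjusted p = 0.28 with an estimated correlation), Oas2 by −1.30 ± 0.17. Alternative activation and repair genes moved both ways, with 4 higher and 14 lower of 32 (4 and 15 over the list alone; median −0.44, 9.5e-04, and 0.30 with an estimated correlation). Among lists of other cells, skeletal muscle genes had 0 higher and 8 lower of 13 (10 lower over the list alone; median −0.65, 3.1e-06, and 0.19 with an estimated correlation), Ckm at −0.91 ± 0.25. Of 3 eosinophil genes, 2 rose (Siglecf by 1.00 ± 0.15 and Alox15 by 1.60 ± 0.24) and Ccr3 did not pass (−0.37). The list had a median of 1.00 (0.012, and 0.055 with an estimated correlation) with 2 higher and 1 lower over the list alone. Dendritic cell genes ranked higher with 5 higher and 2 lower of 13 (6 and 2 over the list alone; median 0.43, 2.4e-04, and 0.051 with an estimated correlation; 0.26 without DTR− replicate 2). Endothelial genes had 3 higher and 0 lower of 7, also over the list alone, and were called higher although their median was −0.04 (0.0069, and 0.051 with an estimated correlation). That median was −0.02 without DTR− replicate 1, and 0.10 and −0.12 without DTR+ replicates 1 and 2. B cell genes had 0 higher and 3 lower of 4, also over the list alone (median −0.63, 4.7e-04, and 0.051 with an estimated correlation). Macrophage genes had 0 higher and 4 lower of 10 (6 lower over the list alone; −0.19, 5.9e-04, and 0.15). Erythroid genes had 1 higher and 0 lower of 2, also over the list alone (1.04, 0.038, and 0.15).

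Of the 6 genes that rose in the 24 h MHCII+ arrays, 6 were among the 589 of the set with no DT time (0.32 by chance), and the 1 gene of the 24 h MHCII− arrays was as well (0.053 by chance). Of the 43 genes of the 8 h MHCII+ arrays 8 were (2.29 by chance), while 0 genes fell in both (0.68 by chance) and 5 went opposite ways. Across all genes the 2 MHCII+ effects at 24 h and with no DT time did not track each other (Pearson correlation 0.0026). The count of 1276 became 567 without DTR+ replicate 1, 636 without DTR− replicate 1 and 743 without DTR− replicate 2; with array quality weights it was 4278, and with a fit on the compared arrays only 3919.

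**Figure D3:**
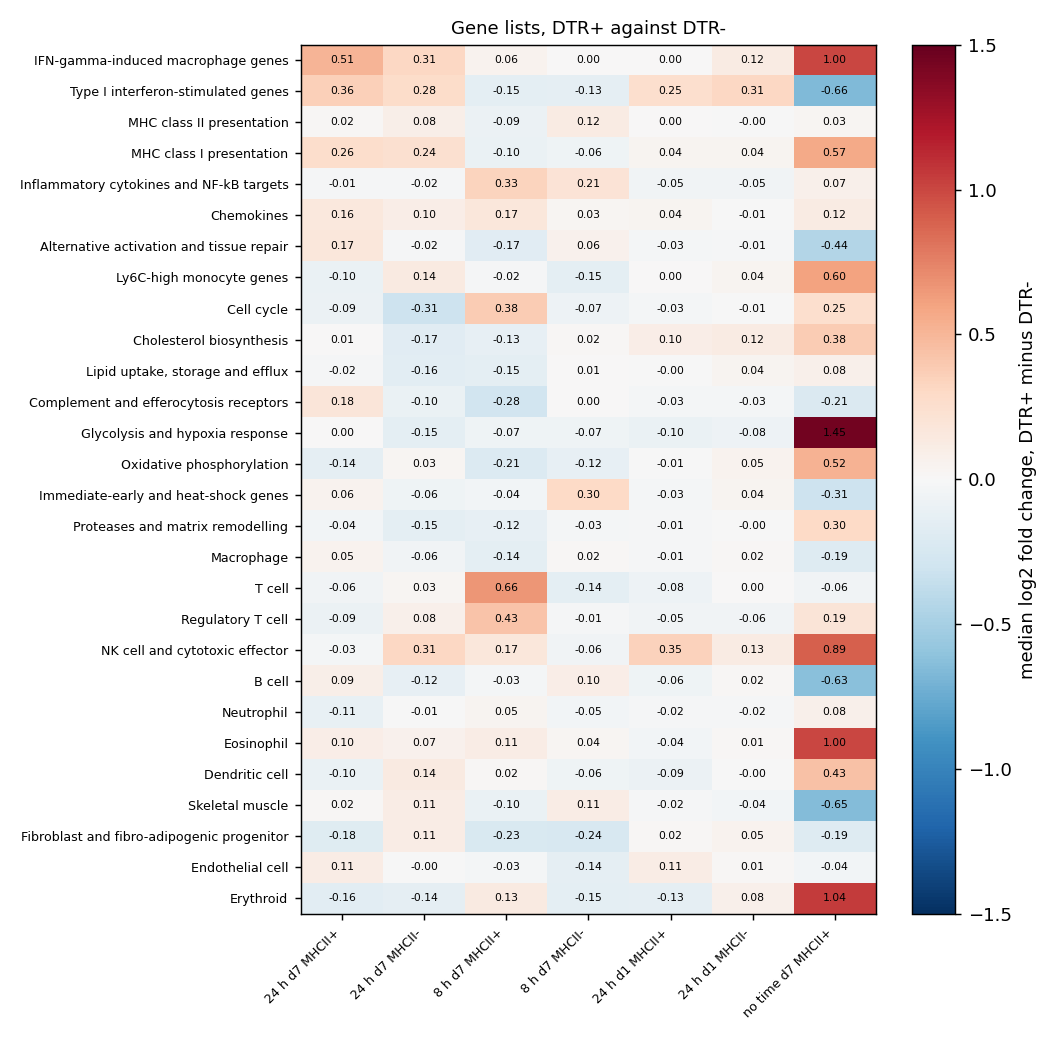
Median log2 difference (colour, −1.5 to 1.5) of the 28 gene lists (vertical axis) in the 7 DTR+ against DTR− comparisons (horizontal axis). The IFN-γ list has medians of 0.51, 0.31 and 1.00 in the 24 h MHCII+, 24 h MHCII− and no-DT-time columns, and glycolysis and hypoxia genes reach 1.45 in the last.

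The next comparisons asked how MHCII+ and MHCII− macrophages of DTR− mice differed. At day 0, 935 genes were higher and 1169 lower in MHCII+ cells (2 against 2 arrays); at day 1, 225 and 46 (2 against 2); at day 4, 124 and 111 (2 against 2); at day 7, 226 and 353 in the 24 h set (4 against 3) and 150 and 95 in the 8 h set (3 against 4). The class II genes by which the cells were sorted were higher each time, H2-Ab1 by 2.73 ± 0.15, 5.78 ± 0.15, 3.33 ± 0.15, 1.76 ± 0.12 and 2.04 ± 0.12 in that order, and H2-Eb1 by 3.70 ± 0.24, 4.92 ± 0.24, 4.05 ± 0.24, 2.50 ± 0.18 and 2.94 ± 0.18. Klrb1b, a C-type lectin-like receptor gene of the NK complex, was higher by 6.17 ± 0.21, 3.86 ± 0.21, 4.73 ± 0.21, 3.96 ± 0.16 and 3.55 ± 0.16. Vsig4, a complement receptor gene of resident macrophages, was lower at days 0, 4 and 7, by −4.34 ± 0.31, −3.52 ± 0.31, −2.97 ± 0.24 (24 h) and −3.07 ± 0.24 (8 h). At day 1 the genes lower in MHCII+ cells included Ly6a2 (−4.41 ± 0.62), the iron-binding Lcn2 (−3.77 ± 0.63) and the acute-phase gene Saa3 (−2.36), and Cd209a (5.69 ± 0.34) and Retnla (5.38 ± 0.32) were higher. At day 7 Il6 was higher by 2.53 ± 0.36 (24 h) and 2.18 ± 0.36 (8 h), and the gelatinase gene Mmp9 lower by −2.04 ± 0.30 and −1.41 ± 0.30.

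Dendritic cell genes ranked higher in MHCII+ cells in each of the 5 comparisons: of 13 members, 12, 9, 9, 9 and 8 were higher and 0 lower (12, 10, 12, 11 and 11 over the list alone), with medians of 1.56, 1.86, 1.46, 0.93 and 0.63 (largest camera adjusted p = 5.1e-19, and 1.9e-05 with an estimated correlation). MHC class II presentation did as well, with 9, 9, 9, 9 and 8 of 15 higher, 2 lower at day 0 and 0 elsewhere (10, 10, 10, 9 and 9 higher over the list alone, with 2 lower at day 0 and 1 at day 4), and medians of 1.01 to 1.63 (largest 7.5e-12, and 5.3e-04 with an estimated correlation). The cell cycle list ranked higher in MHCII+ cells at days 0 and 1, with 11 and 13 of 36 higher and 0 lower (13 and 22 over the list alone; medians 0.55 and 0.79, camera adjusted p = 2.4e-06 and 3.8e-25, and 0.43 and 0.094 with an estimated correlation), Ccna2 by 2.27 ± 0.36 at day 1. It ranked lower at day 4 and in both day 7 sets, with 0 higher and 2, 5 and 6 lower (11, 19 and 24 over the list alone; medians −0.58, −0.45 and −0.53, camera 5.7e-14, 2.6e-07 and 7.2e-21, and 0.28, 0.40 and 0.20 with an estimated correlation), Plk1 by −1.10 ± 0.24 in the 24 h set and Ccnb2 by −1.23 ± 0.24 in the 8 h set. None of these 5 list calls held with an estimated correlation. At day 0, neutrophil genes were lower in MHCII+ cells, 10 of 12, also over the list alone (median −2.37, 1.1e-07, and 0.15 with an estimated correlation), with Ngp at −4.61 ± 0.77 and S100a8 at −3.39 ± 0.64. This difference rested largely on day 0 MHCII− replicate 1: without it the list median was −0.49 (camera adjusted p = 0.0033), Ngp stood at −3.11, S100a8 at −1.21 (0.057), S100a9 at −0.47 (0.52, from −2.73) and Cxcr2 at −0.02 (0.96, from −3.05). Without day 0 MHCII− replicate 2 the list median was −3.61 and S100a8 stood at −5.58. The day 0 cell cycle median was 0.35 without MHCII+ replicate 2.

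Other lists of other cells stood apart between the subsets too. The NK cell and cytotoxic effector list ranked higher in MHCII+ cells in all 5 comparisons, with 2, 2, 2, 2 and 1 of 2 higher (2 each over the list alone; medians 3.04, 2.14, 2.12, 1.84 and 1.19, largest camera adjusted p = 1.7e-05, and 0.012 with an estimated correlation). At day 0, macrophage genes had 4 of 10 lower, also over the list alone (−0.35, 0.0060, and 0.35 with an estimated correlation). Eosinophil genes had 2 of 3 lower, also over the list alone (−0.90, 0.043, and 0.19). The eosinophil call ended without MHCII+ replicate 1 (−0.66, 0.14) or MHCII− replicate 1 (−1.21, 0.052), and the median was −0.59 without MHCII− replicate 2. At day 1, B cell genes had 1 of 4 higher and 2 over the list alone (0.46, 3.8e-04, and 0.042 with an estimated correlation). Neutrophil genes had 2 of 12 lower, also over the list alone (−0.17, 3.4e-05, and 0.27; −0.28 without MHCII+ replicate 2). T cell genes ranked higher at day 4 (0.04, 0.036, and 0.60 with an estimated correlation) and at day 7 of the 24 h set (0.20, 0.0066, and 0.38), each with 1 of 8 higher and 2 over the list alone. The day 4 call ended without MHCII+ replicate 2 (−0.05, 0.35) or MHCII− replicate 1 (0.05, 0.065), and the median was 0.17 without MHCII+ replicate 3 and 0.07 without MHCII− replicate 2. Regulatory T cell genes ranked higher in the same 2 comparisons (0.38, 0.0057, and 0.28 with an estimated correlation; 0.30, 0.049, and 0.40), with 0 of 4 passed, also over the list alone. Their call ended at day 4 without MHCII+ replicate 2 (0.37, 0.056). At day 7 it ended without MHCII+ replicates 2 (0.29, 0.059), 3 (0.24, 0.12) and 4 (0.35, 0.050) or MHCII− replicates 1 (0.26, 0.073) and 2 (0.24, 0.10). At day 7, skeletal muscle genes ranked higher in the 24 h (4 of 13, 12 over the list alone; 0.44, 4.1e-12, and 0.096 with an estimated correlation) and 8 h sets (0 of 13, 2 over the list alone; 0.29, 2.5e-05, and 0.39). So did fibroblast genes in the 24 h (2 of 12, 8 over the list alone; 0.36, 1.0e-07, and 0.11 with an estimated correlation) and 8 h sets (0 of 12, 1 over the list alone; 0.16, 0.0029, and 0.48). The latter call ended without MHCII− replicate 5 (0.07, 0.13).

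In all 5 comparisons 46 genes were higher in MHCII+ cells, among them Klrb1b, Ccl17 (1.82 to 4.88), Cd209a (1.29 to 5.69), the growth factor receptor gene Flt3 (0.63 to 1.96) and the peptidase gene Dpp4 (1.10 to 2.65). The 3 genes lower in all 5 were the gap junction gene Gja1 (−1.70 to −0.97), Lbp (−1.43 to −0.63) and Tfec (−1.70 to −0.52); these 3, Flt3 and Dpp4 were chosen after their values were seen. The day 0 count of 2104 became 947 without MHCII+ replicate 2, and 1343 and 1197 without MHCII− replicates 1 and 2. At day 1, 271 became 178 and 148 without MHCII+ replicates 1 and 2, and 152 and 154 without MHCII− replicates 1 and 2. At day 4, 235 became 114 and 145 without MHCII+ replicates 2 and 3, and 127 and 93 without MHCII− replicates 1 and 2. In the 24 h day 7 set, 579 became 283, 993, 268 and 1352 without MHCII+ replicates 1 to 4 in turn, and 259 and 257 without MHCII− replicates 1 and 2. In the 8 h set, 245 became 152 and 133 without MHCII+ replicates 1 and 2, and with a replicate block it was 568. At day 4, the Mmp9 call (−1.86 ± 0.39) ended without MHCII+ replicate 2 (0.18) or MHCII− replicate 1 (0.14).

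The last comparisons followed DTR− macrophages over days. Days 0 and 1 come from different sets of arrays, so day and set cannot be separated there. The day 1 labels also carry 24 h of DT, while those of days 0 and 4 give no DT time. Day and DT therefore cannot be separated in either step through day 1. From day 0 to day 1, 2063 genes rose and 1884 fell in MHCII+ cells and 1041 rose and 1794 fell in MHCII− cells (2 against 2 arrays each). The matrix proteoglycan gene Vcan rose by 4.84 ± 0.70 in MHCII+ and 4.57 ± 0.70 in MHCII− cells, Chil3 by 3.43 ± 0.55 and 3.23 ± 0.55, and the protease inhibitor gene Timp1 by 3.32 ± 0.49 and 3.22 ± 0.49. The lectin gene Cd209f fell by 4.86 ± 0.52 and 7.75 ± 0.52, and Igf1, a growth factor gene for muscle, by 1.39 ± 0.14 and 2.75 ± 0.14. In MHCII− cells, Vsig4 (−5.72 ± 0.31) and the efferocytosis receptor gene Timd4 (−3.26 ± 0.17) fell. Glycolysis and hypoxia genes rose in MHCII+ cells in 13 of 23 members and 0 fell (13 over the list alone; median 0.72, camera adjusted p = 3.4e-04, and 0.55 with an estimated correlation). In MHCII− cells, complement and efferocytosis receptor genes fell in 14 of 21 and 0 rose (16 over the list alone; median −1.40, 3.8e-12, and 0.087 with an estimated correlation). Repair genes had 3 higher and 19 lower of 32 (3 and 21 over the list alone; median −1.02, 6.9e-13, and 0.084 with an estimated correlation). Ly6C-high monocyte genes had 11 higher and 1 lower of 17 (13 and 1 over the list alone; median 1.15, 9.7e-07, and 0.11 with an estimated correlation). Neutrophil genes had 1 higher and 9 lower of 12, also over the list alone (median −1.94, 0.0075, and 0.55 with an estimated correlation), Ngp at −4.44. Without day 0 MHCII− replicate 1 the list median was −0.19 (0.95) and Ngp stood at −2.94; without replicate 2 the median was −2.95. Among lists of other cells in MHCII+ cells, dendritic cell genes fell in 12 of 13 and 0 rose (13 over the list alone; median −0.96, 6.5e-05, and 0.078 with an estimated correlation). B cell genes fell in 3 of 4, also over the list alone (−1.14, 6.3e-04, and 0.078). Skeletal muscle genes had 0 higher and 5 lower of 13 (−0.38, 0.0044, and 0.55 with an estimated correlation), fibroblast genes 1 and 4 of 12 (−0.23, 0.010, and 0.55) and endothelial genes 0 and 4 of 7 (−0.58, 0.032, and 0.31), each the same over the list alone. Without day 0 replicate 1 these 3 calls ended (−0.27, 0.057; −0.26, 0.057; −0.37, 0.14), and the endothelial call also without day 1 replicate 2 (−0.37, 0.062). The muscle median was −0.61 without day 0 replicate 2 and the fibroblast median −0.15 without day 1 replicate 1. In MHCII− cells, B cell genes fell in 4 of 4, also over the list alone (−1.35, 8.0e-06, and 0.024 with an estimated correlation). Eosinophil genes fell in 2 of 3, also over the list alone (−1.16, 0.026, and 0.11). Muscle genes had 0 higher and 7 lower of 13 (8 over the list alone; −0.60, 0.0031, and 0.55 with an estimated correlation). Fibroblast genes had 0 and 4 of 12, also over the list alone (−0.21, 0.029, and 0.59). Their call ended without day 0 replicate 1 (−0.24, 0.061). The MHCII+ count of 3947 became 2426 without day 0 replicate 2 and 2337 without day 1 replicate 1. The MHCII− count of 2835 became 1673 without day 0 replicate 1 and 1753 and 1810 without day 1 replicates 1 and 2.

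From day 1 to day 4, 861 genes rose and 843 fell in MHCII+ cells, and 1870 rose and 810 fell in MHCII− cells (2 against 2 arrays each). Hpgd rose by 3.30 ± 0.25 and Cxcl9 by 2.95 ± 0.43 in MHCII+ cells, and Cxcl9 rose by 2.36 ± 0.43 in MHCII− cells. Igf1 rose by 1.60 ± 0.14 and 2.95 ± 0.14, and Arg1 fell by 3.27 ± 0.61 and 3.35 ± 0.61. Vsig4 (3.38 ± 0.31), the proliferation gene Mki67 (2.65 ± 0.34) and the cyclin gene Ccna2 (4.05 ± 0.36) rose in MHCII− cells. Cell cycle genes rose there in 31 of 36 members and 0 fell (36 over the list alone; median 1.30, camera adjusted p = 1.5e-18, and 0.24 with an estimated correlation). Complement and efferocytosis receptor genes rose in 9 and 13 of 21 and 0 fell (10 and 13 over the list alone; medians 0.34 and 0.88, 4.2e-05 and 3.4e-07, and 0.35 and 0.24 with an estimated correlation). IFN-γ-induced genes had 14 and 15 higher of 34 and 1 lower in each subset (16 and 16 higher, 2 and 1 lower over the list alone; medians 0.42 and 0.41, 1.4e-06 and 0.0012, and 0.31 and 0.45 with an estimated correlation). Glycolysis and hypoxia genes fell in 9 and 13 of 23 and 0 rose (13 and 13 over the list alone; medians −0.51 and −0.54, 5.6e-06 and 5.5e-07, and 0.35 and 0.34 with an estimated correlation). Among lists of other cells, skeletal muscle genes had 6 and 6 of 13 higher (7 and 7 over the list alone; medians 0.51 and 0.51, 5.6e-06 and 9.6e-04, and 0.35 and 0.47 with an estimated correlation). Fibroblast genes had 5 and 7 of 12 higher (8 and 7 over the list alone, with 1 lower in MHCII+ cells; 0.53 and 0.45, 7.6e-05 and 0.0023, and 0.35 and 0.45). B cell genes had 3 and 3 of 4 higher (3 and 4 over the list alone; 1.03 and 1.56, 4.2e-05 and 2.4e-05, and 0.057 and 0.041 with an estimated correlation). In MHCII+ cells dendritic cell genes had 4 higher and 1 lower of 13, also over the list alone (0.25, 0.013, and 0.35 with an estimated correlation; 0.16 without day 1 replicate 2). The day 1 arrays stand in both time steps, so a fall after a rise is not independent of it. Their labels carry 24 h of DT and those of day 4 no DT time, so these changes may not reflect time alone. The MHCII+ count of 1704 became 787 and 924 without day 1 replicates 1 and 2 and 656 without day 4 replicate 2. The MHCII− count of 2680 became 1692 and 1536 without day 1 replicates 1 and 2, and 1678 and 1582 without day 4 replicates 1 and 2.

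From day 0 to day 7, in MHCII+ arrays with no DT time (same age and gate as day 0), 1157 genes rose and 966 fell (2 against 2 arrays). Atp6v0d2, a proton pump subunit gene, rose by 2.68 ± 0.15, the phosphatase gene Acp5 by 2.39 ± 0.23, the metalloprotease gene Mmp14 by 2.42 ± 0.24 and the lipid-sensing receptor gene Trem2 by 1.26 ± 0.14. Ccl17 fell by 3.75 ± 0.30, Klrb1b by 3.54 ± 0.21 and Il6 by 3.35 ± 0.47. Type I interferon-stimulated genes rose in 23 of 26 members and 0 fell (25 over the list alone; median 1.02, camera adjusted p = 5.1e-13, and 0.24 with an estimated correlation), Ifit2 by 2.84 ± 0.46. Dendritic cell genes had 1 higher and 10 lower of 13, also over the list alone (median −1.20, 2.6e-10, and 0.0021 with an estimated correlation). Cell cycle genes had 0 higher and 14 lower of 36 (23 lower over the list alone; median −0.72, 1.6e-09, and 0.42 with an estimated correlation), and skeletal muscle genes 8 higher and 0 lower of 13 (8 over the list alone; median 0.86, 7.7e-07, and 0.26 with an estimated correlation), Acta1 by 1.74 ± 0.24. Macrophage genes had 5 higher and 0 lower of 10 (0.34, 9.6e-04, and 0.24 with an estimated correlation), the NK cell list 2 of 2 lower (−1.98, 0.0013, and 0.090) and endothelial genes 4 of 7 lower (−0.46, 0.0024, and 0.048), each also over the list alone. The cell cycle median was −0.46 without day 0 replicate 2. The count of 2123 became 969 without day 0 replicate 2, and 1239 and 1174 without day 7 replicates 1 and 2.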

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

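The tests of eosinophils in the day 7 set with no DT time, of T cells and of effect size in the 8 h MHCII+ arrays, and of a single wrong label and of replicate number ranges in the 8 h MHCII− arrays, with a score from genes chosen again, were chosen only after the result was seen.

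In the day 7 set with no DT time in its labels, 1276 genes differed between DTR+ and DTR− MHCII+ macrophages, where the 24 h and 8 h MHCII+ arrays gave 6 and 54. For eosinophils among the sorted cells, the median of the 8 eosinophil genes was 0.050, which met what had been set against them. Epx stood at 6.01 against 5.95 and Prg2 at 6.33 against 6.41 (DTR+ against DTR−). Both lie below the filter of 7.57, so their flat values decide little. Siglecf (1.00) and Alox15 (1.60) rose and the gate lists no SiglecF step, so eosinophils stay open. Quantile normalization applied again gave 1399 genes, which argues against a shift of whole arrays. Of the genes that rose, 70.0% were above 0 in the 24 h MHCII+ arrays, against 59.4% of all genes. This met what had been set for a genotype effect shared with that set. Of those that fell, however, 24.0% were below 0 there, which argues against such an effect for the fall. Most of the genes that fell were thus above 0 there too. The share does not follow the direction of change, so it decides nothing on the rise. A different DT schedule stays open and was not tested, because the labels give no DT time for this set.

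In the 8 h set, T cell genes were high in 1 of the 3 DTR+ MHCII+ arrays, replicate 1: the median excess of the T cell list in that array over the other 2 was 1.43, with Cd3g at 10.83 against 5.60, Cd3e at 9.82 against 7.50 and Thy1 at 9.70 against 7.68, while the macrophage list lay below the other 2 in 10 of 10 members. Regulatory T cell genes were high there too (7 of 7 members, median excess 1.11), although DTR+ stands for their removal, and so were cell cycle genes (35 of 37, 0.96); this may reflect T cells among the sorted cells of that array, which the gate for F4-80 and CD11b was meant to leave out. Without that array 9 genes were called and not 54, fewer than without either other DTR+ array (778 and 19), which met what had been set for these calls to depend on it; leaving out DTR− replicate 1 or 2 gave 5 and 8, so the dependence is not on this array alone. The median change of the 43 genes that rose was 95.6% of its size without that array. These genes were called with that array included, and a gene high in that array alone widens its own spread and hardly passes. This share was therefore largely fixed by the choice of genes and decides nothing on the array as their source. What else the array holds, whether its genotype label is right and whether T cells differed between the mice stay open with 1 such array.

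In the 8 h MHCII− arrays, DTR− replicate 5 correlated best with DTR+ replicates 5 and 6 (0.995 and 0.992, against 0.976 to 0.979 with DTR− replicates 1 to 3), and DTR+ replicate 3 correlated at 0.983 to 0.989 with DTR− replicates 1 to 3. On a score of the genes changed at 8 h in MHCII+ arrays, which had been set to test exchanged labels between DTR+ replicate 3 and DTR− replicate 5, 2 arrays were out of place, and DTR− replicate 5 scored 0.92. These genes were chosen against DTR− MHCII+ replicates 1 to 3, and same-numbered DTR− samples deviate together, so the low scores of DTR− replicates 1 to 3 (0.29, 0.23 and 0.38) may follow from shared samples and the score decides neither an exchange nor a wrong label on DTR− replicate 5 alone. With 54 genes chosen again without the same-numbered MHCII+ array, DTR− replicates 1 to 3 stood at −0.58, −0.77 and −0.63 from DTR+ replicates 5 and 6, DTR+ replicate 3 at −0.33 and DTR− replicate 5 at −0.15 to −0.08, which leaves DTR+ replicate 3 between the others. An exchange, a wrong label and batches that follow replicate numbers 1 to 3 and 5 to 6 stay open: 20.0% of genes differed between these ranges with genotype in the same fit, but the ranges are the 2 clusters already seen in the correlations, so this value decides nothing, and the labels give no batch.

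Tests for an array apart from its group were run only in the groups of 4 arrays, 24 h DTR− MHCII+ and 8 h DTR− MHCII−. Arrays of smaller groups could not be flagged. Of these 84 tests 1 passed, where chance would give about 1 in 20, so the flag is no more than chance gives. The neutrophil list lay at 7.79 in the DTR− MHCII+ replicate 3 of the 24 h set, against 6.88 to 7.00 in the other 3.

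Lists whose genotype effect differed by camera are given with their median difference, and in each case the call did not hold with an estimated correlation. Many also changed when 1 array was left out. In the 24 h set, MHCII+ minus MHCII−, they were Ly6C-high monocyte genes (−0.18), oxidative phosphorylation (−0.17) and fibroblast genes (−0.34). The Ly6C call was lost without any 1 of 10 of the 12 arrays, all but DTR− replicate 3 of either subset (−0.21 to −0.07 in these 10), and the median was −0.38 without DTR− MHCII− replicate 3. Without DTR+ MHCII+ replicate 5 the other 2 calls were lost (−0.07, adjusted p = 0.19, and −0.11, 0.12). Oxidative phosphorylation stood at −0.45 without DTR+ MHCII+ replicate 1, and fibroblast genes at −0.20 without DTR− MHCII+ replicate 1 and −0.22 without DTR− MHCII− replicate 3.

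In the 8 h set the lists were NF-κB targets (0.18), repair (−0.22), cell cycle (0.47), complement and efferocytosis receptors (−0.28), immediate-early (−0.29), macrophage (−0.17), T cell (0.67) and regulatory T cell genes (0.57). Without DTR+ MHCII+ replicate 1, the array with high T cell genes, 5 calls were lost: repair (−0.05, adjusted p = 0.28), complement (−0.05, 0.66), immediate-early (−0.12, 0.065), macrophage (−0.13, 0.26) and regulatory T cell genes (0.05, 0.43). Cell cycle and T cell genes stayed past the threshold there at 0.15 (0.0024) and 0.19 (0.020). The NF-κB call was lost without DTR+ MHCII+ replicate 3 (0.10) or 4 (0.11), DTR− MHCII+ replicate 1 (0.14), DTR+ MHCII− replicate 6 (0.06) or DTR− MHCII− replicates 3 (0.07) and 5 (0.07), and stood at 0.10 without DTR− MHCII− replicate 1 or DTR+ MHCII− replicate 5. The repair call was also lost without DTR− MHCII+ replicate 2 (−0.19, 0.069) or DTR− MHCII− replicate 3 (−0.23, 0.10). The complement call was also lost without DTR− MHCII+ replicate 2 (−0.27, 0.11), DTR+ MHCII− replicates 3 (−0.09, 0.091) and 5 (−0.31, 0.057) or DTR− MHCII− replicates 3 (−0.22, 0.24) and 5 (−0.22, 0.050). Without DTR+ MHCII+ replicate 3, repair and complement stood at −0.38 and −0.42. The macrophage call was also lost without DTR− MHCII+ replicates 1 and 2, DTR+ MHCII− replicates 3 and 5 or DTR− MHCII− replicates 3 and 5 (−0.22 to −0.16).

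For 24 h minus 8 h in MHCII+ arrays the lists were IFN-γ-induced (0.46), type I interferon-stimulated (0.48), MHC class I (0.32), NF-κB (−0.29), repair (0.32), cell cycle (−0.43), complement (0.39), T cell (−0.69) and regulatory T cell genes (−0.48). Without 8 h DTR+ replicate 1 the calls of repair (0.19, adjusted p = 0.13), complement (0.14, 0.082) and regulatory T cell genes (−0.19, 0.22) were lost, T cell genes stood at −0.19 (0.024) and cell cycle genes at −0.16. The latter stood at −0.66 and −0.18 without 24 h DTR+ replicates 1 and 5.

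In MHCII− arrays the lists were IFN-γ-induced (0.35), type I interferon-stimulated (0.36), MHC class I (0.29), NF-κB (−0.36), Ly6C-high monocyte (0.15), oxidative phosphorylation (0.13), immediate-early (−0.38) and fibroblast genes (0.33). The NF-κB call was lost without 24 h DTR+ replicate 1 (−0.36, adjusted p = 0.073), 24 h DTR− replicate 3 (−0.26, 0.13), 8 h DTR+ replicate 3 (−0.25, 0.072) or 8 h DTR− replicate 2 (−0.26, 0.074), and that of oxidative phosphorylation without 8 h DTR+ replicate 5 (0.03, 0.061). IFN-γ-induced genes stood at 0.23 and 0.56 without 24 h DTR+ replicates 1 and 3, and immediate-early genes at −0.21 without the latter. MHC class I stood at 0.19 without 24 h DTR+ replicate 1, and at 0.45 and 0.17 without 8 h DTR+ replicates 3 and 5. Ly6C genes stood at 0.36 without 24 h DTR− replicate 3, 0.24 without 8 h DTR+ replicate 6, and 0.56 and 0.06 without 8 h DTR− replicates 2 and 3. Oxidative phosphorylation stood at 0.23 without 24 h DTR+ replicate 3, 0.25 and 0.06 without 8 h DTR+ replicates 3 and 6, and 0.08, 0.07 and 0.22 without 8 h DTR− replicates 1, 3 and 5.

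Probe sets that name no single gene were outside the comparisons; of 1860 such sets tested, 4 differed by genotype in 24 h MHCII+, 3 in 24 h MHCII−, 10 in 8 h MHCII+ and 144 in the MHCII+ arrays with no DT time.

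Other splits of the same arrays were counted for each comparison of at least 3 against 3. For 24 h MHCII− arrays and 8 h MHCII+ arrays there are 10 splits, too few for a share under 0.05: as many genes came from 1 of 10 at 24 h (real 1, highest other 0) and 1 of 10 at 8 h (real 54, highest other 1), and as large a median from 2 of 10 for the IFN-γ list at 24 h (real 0.31, highest other 0.31) and 2 of 10 for NF-κB targets at 8 h (real 0.33, highest other 0.34). For 8 h MHCII− arrays chance is not excluded: 7 of 35 splits gave as many genes (real 2, highest other 1612), and 6 of 35 as large a median of NF-κB targets (real 0.21, highest other 0.31). The split with 1612 genes sets DTR+ replicates 5 and 6 and DTR− replicate 5 against the rest and points to a structure of the samples. For MHCII+ against MHCII− in the 8 h set 1 of 35 splits gave as many genes (real 245, highest other 105). The numbers pair these samples, however, and only 8 splits part the 3 pairs, too few for a share under 0.05; the highest other among them gave 63. In the 24 h set 3 of 35 splits gave as many genes (real 579, highest other 1478). The splits with more genes move MHCII+ replicate 4 or 2 to the MHCII− side and again point to a structure of the samples. They keep the other arrays as they were and so most of the real contrast, so this count decides nothing on chance. The 46 genes higher in MHCII+ cells in all 5 comparisons argue against chance for those genes. For the difference of effects between subsets at 8 h, and between 24 h and 8 h in MHCII− arrays, the real count is 0, so 100 of 100 splits had to give at least as many and their number decides nothing; the highest others, 1494 and 1473, point to a structure of the samples.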

How the results depend on the processing

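Leaving out 2 arrays that stand apart (24 h DTR+ MHCII− replicate 3 and 8 h DTR+ MHCII+ replicate 1) and a term for replicate number ranges were chosen only after the result was seen. The IFN-γ list stayed higher and past its threshold in every alternative run for 24 h MHCII+, 24 h MHCII− and the day 7 set with no DT time. Counts of genes moved far more; the cause was not tested. The looser filter at 120 moved no count by more than 1.5 times. Of 588 list results, 469 were the same with fry, 103 were weaker and 16 stronger than in the main run.

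With array quality weights the counts were 1 for 24 h MHCII+, 880 for 24 h MHCII−, 2103 for 8 h MHCII+, 2492 for 8 h MHCII−, 34 for day 1 MHCII− and 4278 for the day 7 set with no DT time. For MHCII+ against MHCII− they were 1181 at day 1, 378 at day 4 and 937 at day 7 of the 8 h set. For days in DTR− mice they were 4861 (day 1 against 0, MHCII−), 5934 (day 4 against 1, MHCII−) and 3941 (day 7 against 0, MHCII+). For differences of effects they were 1440 (8 h, between subsets) and 2139 (MHCII−, between sets). The protease list of 24 h MHCII− arrays changed sign to 0.014, from −0.15.

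With a fit on the compared arrays only, the genotype counts were 0 and 0 at 24 h (MHCII+ and MHCII−), 2 and 0 at 8 h, 1 for day 1 MHCII− and 3919 with no DT time. Others were 936, 402 and 222 for the subsets at day 1, day 4 and day 7 (24 h set), 5566 for day 4 against 1 in MHCII− cells, and 1 for the difference between sets in MHCII+ cells. Smaller residual degrees of freedom go with this setting by construction. The spread is then also that of the compared arrays alone. The residual SD was 0.20 in the 24 h day 7 set, 0.10 at day 0 and with no DT time, and 0.11 at days 1 and 4. Over all arrays it was 0.16. What moved the counts was not tested.

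Without the 2 arrays that stand apart, counts were 16 and 12 for 24 h MHCII+ and MHCII−, 27 and 18 for 8 h MHCII+ and MHCII−, 363 and 1086 for the subsets at day 4 and day 7 (24 h set), and 1 and 1 for the differences between subsets at 24 h and between sets in MHCII− cells. The lipid list of 24 h MHCII− arrays changed sign to 0.038, from −0.16. Quantile normalization again gave 2 for 24 h MHCII−, 1 for 8 h MHCII− and 5 for the difference between sets in MHCII+ cells. With no filter, 24 h MHCII+ gave 3 and the difference between subsets at 8 h gave 1. With the number range as a term in a fit on the compared arrays only, 2 choices together, 8 h MHCII− gave 0, the same count as that fit without the term.

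With a replicate block, counts were 11 for 24 h MHCII−, 590 for 8 h MHCII+ and 0 for 8 h MHCII− by genotype, and 3713 at day 0, 534 at day 1, 2850 at day 7 of the 24 h set and 568 at day 7 of the 8 h set by subset. Only in the last did the paired numbers bear out a block. No paired analysis was possible because fewer than 2 numbers were shared, or the sets differed, for 24 h MHCII+ by genotype, day 4 by subset, day 1 against day 0 in both subsets, day 4 against day 1 in MHCII+ cells, the difference between subsets at 24 h and that between sets in MHCII+ cells.

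Leaving out each array in turn gave 0 to 10 genes for 24 h MHCII+, 0 to 12 for 24 h MHCII−, 5 to 778 for 8 h MHCII+, 0 to 97 for 8 h MHCII−, 0 to 0 for both subsets at day 1 and 567 to 875 with no DT time. By subset the ranges were 947 to 1845 at day 0, 148 to 178 at day 1, 93 to 145 at day 4, and 257 to 1352 and 133 to 245 at day 7 (24 h and 8 h sets). Over days they were 2337 to 3178 and 1673 to 2131 for day 1 against 0 (MHCII+ and MHCII−), 656 to 1676 and 1536 to 1692 for day 4 against 1, and 969 to 2013 for day 7 against 0. Differences of effects ran from 0 to 1 and 0 to 0 between subsets (24 h and 8 h), and 0 to 55 and 0 to 12 between sets (MHCII+ and MHCII−). Where 1 array of a group was left, the lone sample is assumed to vary like the other groups.

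List medians that changed sign without 1 array included cell cycle in 24 h MHCII+ (−0.30 to 0.17, from −0.09) and day 1 MHCII+ arrays (−0.22 to 0.16, from −0.03; 0.12 without DTR− replicate 2), and type I interferon-stimulated genes at day 0 by subset (−0.81 to 0.20) and for day 1 against 0 in MHCII− cells (−0.59 to 0.45). Neutrophil genes for day 1 against 0 in MHCII− cells ran from −2.95 to −0.19, the latter without day 0 MHCII− replicate 1, where the direction of the test reversed. Other medians past their threshold in the full fit changed sign without 1 array too, among them oxidative phosphorylation and fibroblast genes in 24 h MHCII+ arrays without DTR+ replicate 5 (from −0.14 to 0.00 and from −0.18 to 0.05). Signal over background limits the genes tested: 11074 of 19752 lay above the filter, and Foxp3 and Ifng did not.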

Other observations

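The test of the day 1 arrays' own spread was chosen before its result was seen; no test in this part was chosen only after.

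Beyond the groups described above, cholesterol synthesis genes rose in the day 7 MHCII+ set with no DT time in 5 of 18 members and 0 fell (7 over the list alone; median 0.38, camera adjusted p = 6.8e-06, and 0.19 with an estimated correlation), Sqle by 1.04 ± 0.19 and Cyp51 by 0.80 ± 0.18. Oxidative phosphorylation genes rose in 6 of 27 and 0 fell (11 over the list alone; median 0.52, 1.7e-07, and 0.19 with an estimated correlation), among them Cox5b by 0.68 ± 0.14. Among proteases and matrix genes 8 of 23 rose and 1 fell (10 and 2 over the list alone; median 0.30, 2.2e-04, and 0.22 with an estimated correlation), with Timp1 at 3.46 ± 0.49, the collagenase gene Mmp13 at 2.43 ± 0.25 and the transglutaminase gene Tgm2 at 2.30 ± 0.40. Of the 10 macrophage genes already described for this set, 0 rose and 4 fell (6 over the list alone; median −0.19, 5.9e-04, and 0.15 with an estimated correlation), Cx3cr1 by −2.15 ± 0.18 and C5ar1 by −1.04 ± 0.19. The vascular receptor gene Flt1 rose by 3.71 ± 0.13, and the B cell adaptor gene Bank1 fell by 2.22 ± 0.19.

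From day 1 to day 4, genes listed for other cells rose in the macrophages of DTR− mice. Day and DT label cannot be separated in this step. B cell genes rose in 3 of 4 members in both subsets and 0 fell (3 and 4 over the list alone; medians 1.03 and 1.56, camera adjusted p = 4.2e-05 and 2.4e-05, and 0.057 and 0.041 with an estimated correlation), Cd22 by 1.60 ± 0.18 and 1.76 ± 0.18 and Cd79b by 1.27 ± 0.22 and 1.35 ± 0.22 in MHCII+ and MHCII− cells. Fibroblast genes rose in MHCII+ cells in 5 of 12 members and 0 fell (8 and 1 over the list alone; median 0.53, camera adjusted p = 7.6e-05, and 0.35 with an estimated correlation), with Bgn at 2.53 ± 0.28, Postn at 2.28 ± 0.40 and Sparc at 1.60 ± 0.33, and these 3 genes rose in MHCII− cells by 2.82 ± 0.28, 2.60 ± 0.40 and 2.00 ± 0.33. Skeletal muscle genes rose in 6 of 13 members in both subsets and 0 fell (7 and 7 over the list alone; medians 0.51 and 0.51, camera adjusted p = 5.6e-06 and 9.6e-04, and 0.35 and 0.47 with an estimated correlation), Myl1 by 3.34 ± 0.33 in MHCII+ cells. The lipid transfer gene Pltp rose by 1.02 ± 0.15 and 3.12 ± 0.15, and the scavenger receptor gene Msr1 fell by 0.61 ± 0.10 and 0.72 ± 0.10.

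Fewer genes than chance gives had an unadjusted p under 0.05 between DTR+ and DTR− at day 1 (25 and 154 of 11074, where 554 are expected). A candidate explanation is that the spread shared over all sets is wider than that of the day 1 arrays. The residual SD was 0.11 at days 1 and 4 against 0.16 over all arrays, so the shared spread was indeed wider than theirs. Fitted on the day 1 arrays alone, 308 and 1486 genes had an unadjusted p under 0.05 (2.78% and 13.4%) and 0 and 1 passed. The lower share, 2.78%, stayed below the 5% of chance while the other rose above it. Whether the wider spread accounts for all of the shortfall in MHCII+ macrophages therefore stays open.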
